A study of Mus musculus with 12 samples.

How the data were processed

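Read depth along the ribosomal RNA (rRNA) precursor was measured by total RNA sequencing in 12 libraries, 3 in each of 4 groups. Per the labels' protocols, Hepa1c1c7 cells received luciferase control or Eif3m siRNA at 10 uM for 3 days, and FVB/N mice of 6 to 8 weeks received the same 2 kinds of siRNA in LNP (lipid nanoparticle) formulations at 0.5 mg/kg through the tail vein for 13 days. RNA of the cells came from a nuclear RNA purification kit, whereas RNA of the livers was extracted with phenol and chloroform from frozen ground tissue, per the labels' protocols. Libraries were made with a Clontech pico kit with its ZapR step, which normally removes rRNA sequences, left out. Cells and livers therefore differ in source, RNA fraction, dose and time at once.

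The authors deposited 1 table of coverage signal: for each of 13400 consecutive positions of 1 reference sequence, the whole number of reads over that position in each library, with no scaling to library size. Each column was matched to its sample by the code in the sample title, and 0 columns were left unused. BWA 0.7.12 and SAMtools 1.3 are named in the submitters' processing notes. Their options, the handling of duplicates and multiply mapped reads, the name of the reference sequence and the read length are not given in the sources used here. Multiply mapped reads matter because rRNA genes are repeated. The 85 empty cells of the deposited table, all in liver columns, were read as a depth of 0. Highest depths lay between 149422 and 691208, each at a single position, so the depth was not cut off at a ceiling, and the alternative planned for such a ceiling was not needed.

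The file carries no annotation, so the regions were placed from steps in the depth profile, without regard to group. log2(depth + 1) was averaged over the 12 libraries, and the step at a position was the mean of the 20 nt to its right minus that of the 20 nt to its left. The 3 largest rises that did not fall back within 100 nt opened the mature regions, and the largest fall before the next rise closed each. The condition on falling back was added after the data were seen, because of a spike of depth at positions 414 to 449. Names follow the textbook order of the precursor: 5′ external transcribed spacer (5′ETS), 18S, internal transcribed spacer 1 (ITS1), 5.8S, ITS2, 28S and 3′ external transcribed spacer (3′ETS). Positions count from 1 at the start of the reference sequence. On 1200 edges of simulated profiles the procedure placed 100% within 5 nt. The simulated steps were larger than the real ones, which ran from 1.88 at the end of 5.8S to 5.50 at the end of 28S (log2). The simulation therefore does not show that the real edges are placed as closely.

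For each library, 13 ratios between mean depths of regions were taken, which cancels sequencing depth. Differences of mean log2 ratios were tested with exact two-sided permutation tests and Benjamini-Hochberg adjustment over the 13 ratios. Within cells or liver, 3 against 3 gives 20 assignments and no p below 0.1. Over both systems, labels were exchanged within each system, which gives 400 assignments and a smallest p of 0.005. The planned test of the difference between systems used the same exchange, which keeps a change that both systems share. After the data were seen, a form that first removes that change from the knockdown libraries was added. limma 3.58.1 on the table of ratios was an alternative. In 200 simulated tables of ratios, the stratified test called 99.9% of ratios changed 2-fold and 2.5% of unchanged ones. In 200 further simulations, 5 ratios changed 2-fold in cells alone and the other 8 in both systems alike. The planned test of the difference gave p under 0.05 for 40.7% of the former and 0% of the latter, and the added form, which is not exact, for 92% and 9.94%. The same removal was applied to the splits of the bin fit, and in 100 simulations of bins with equal changes and a shared spacer shift the share of splits fell under 0.05 in 3, against 1 without the removal. Only 10 of these 100 simulations made any call.

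Profiles were compared in 134 bins of 100 nt. Each library was scaled to its summed depth, bins with a mean depth under 10 were left out, and log2(scaled depth + 1) was fitted with limma (lmFit, eBayes with trend) in R 4.3.3, with a threshold of 0.05 on the Benjamini-Hochberg adjusted p. Fold changes of bins are on that log2(depth + 1) scale. Cells and liver were fitted apart; the common change and the difference between systems were fitted over all 12 libraries. Regions were tested as sets of the bins that lie wholly inside them with limma's fry, a rotation test that keeps the correlation between bins. Bins share reads with their neighbours, and all spacer bins of a library move together, so limma's adjusted p-values for single bins are smaller than 3 libraries per group warrant. On simulated data without any change but with such a shared shift, 11 of 100 simulations of the cells fit called at least 1 bin, with a mean of 0.62 of 134 bins; for the liver fit it was 9 of 100, with a mean of 0.46 of 131 bins. fry called at least 1 region in 0 of 100 simulations for cells and in 8 of 100 for liver. These simulations drew the noise of single bins below its fitted SD and shifted only spacer bins together. Their rates therefore do not cover mature bins that move together. With 20 bins changed independently, limma called 90% of those changed by 0.5 and 100% of those changed by 1 on the log2 scale in the cells fit (10 bins each), and 80% and 90% in the liver fit.

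Mean depth per position ran from 10462 to 15537 reads in the cell libraries and from 26971 to 46799 in the liver libraries. Without the read length depths do not convert to numbers of reads, so no counting interval is given. Precision of ratios and segments is shown by the spread between libraries. Standard errors of bins, and of ratio differences credited to limma, are limma's and borrow from the whole fit. For bins they mostly follow the depth trend, with 406 prior against 4 residual degrees of freedom in cells and infinite prior ones in liver. They can lie below the spread between libraries: 0.11 at 3901 to 4000 in cells, against 0.20 for the 5′ETS after its first 650 nt. Liver spacers rested on few reads: mean 3′ETS depth there was 5.37 to 16.5. The labels do not say that replicates came from separate cultures, so p-values for cells measure the spread between these samples, which may be technical.

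The designs, the tests and most alternatives were fixed before the data were examined. The rule for named items covered every region and, per bin comparison, up to 5 bins in each direction with the largest change past the threshold. Alternatives were other depth summaries (median, trimmed edges, a pseudocount of 10 reads), other bins (50 and 200 nt), filters, pseudocounts and scalings, fits with a replicate block, and each replicate left out in turn. Replicate numbers are shared between groups. The data hold no messenger RNA, so the level of Eif3m itself could not be checked here, and gene groups and cell type markers were not analysed here. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.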

Results

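The study concerns knockdown of eIF3m, a subunit of the translation initiation factor eIF3, and the making of ribosomal RNA (rRNA). rRNA was sequenced without depletion from Hepa1c1c7 cells, a mouse hepatoma line, and from livers of FVB/N mice, each after control (luciferase) or Eif3m siRNA, with 3 libraries per group. The precursor transcript holds 18S, 5.8S and 28S rRNA and 4 spacers that are cut out and degraded during maturation. Depth over a spacer was therefore read as unfinished or discarded precursor RNA, and depth over a mature region mostly as finished rRNA. Other sources of spacer depth, among them that of a narrow spike in the first spacer, are weighed below. Mean depth per position was 10462 to 13375 reads in control cells, 13154 to 15537 in Eif3m siRNA cells, 26971 to 44498 in control livers and 41958 to 46799 in Eif3m siRNA livers. These data hold no messenger RNA, so the knockdown itself was not measured here.

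Steps of the depth profile placed 18S at positions 4006 to 5882, 5.8S at 6877 to 7029 and 28S at 8121 to 12837 of the 13400-nt reference. The 5′ external transcribed spacer (5′ETS) before 18S was 4005 nt long, internal transcribed spacer 1 (ITS1) 994 nt, ITS2 1091 nt and the 3′ external transcribed spacer (3′ETS) 563 nt. A further rise of 2.02 on the log2 scale lay at position 651, next to the primary cleavage site of the mouse 5′ETS, and the 5′ETS was read as the first 650 nt and the 3355 nt after them. Spacers held 3.16% ± 0.55 (SD, n = 3) of summed depth in control cells, whose RNA was nuclear, and 0.115% ± 0.012 (SD, n = 3) in control livers, whose RNA was of whole tissue.

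**Figure D1:**
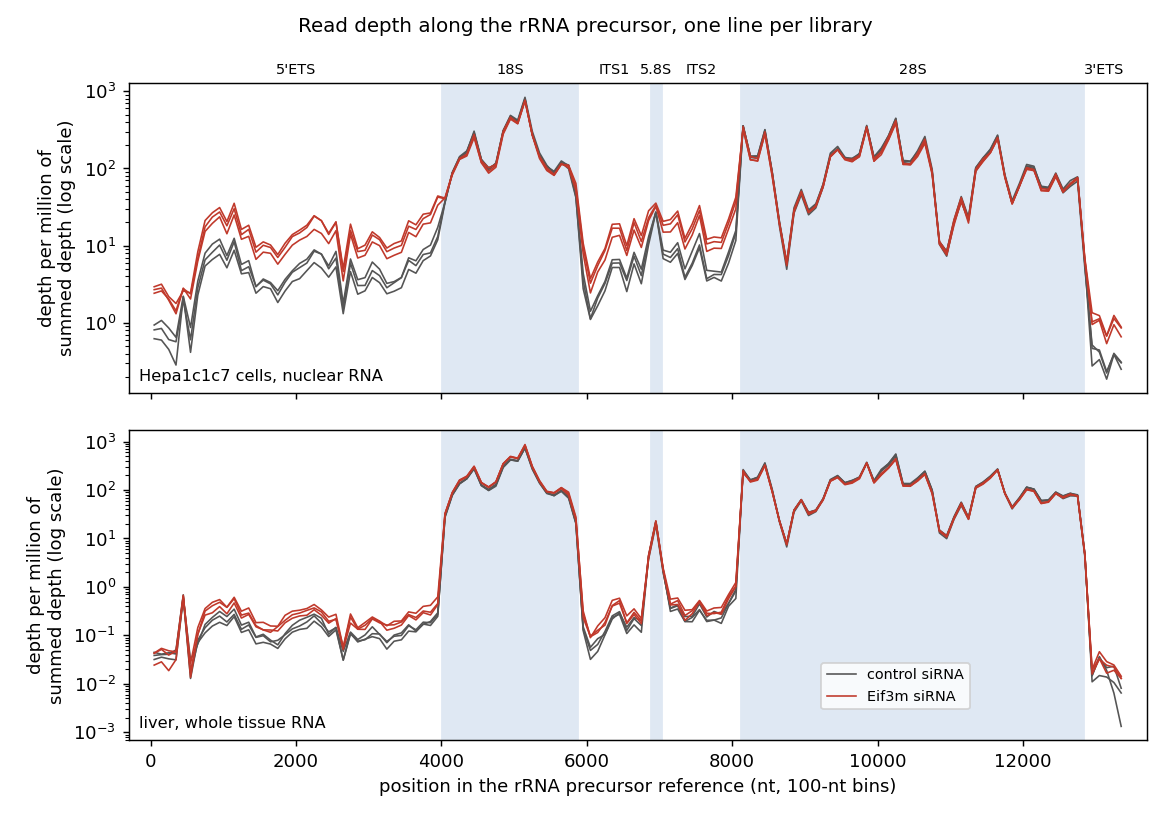
Mean read depth in 100-nt bins along the rRNA precursor, scaled to each library's summed depth, on a log axis, with 1 line per library for cells (upper panel) and liver (lower panel) and the mature regions shaded. Eif3m siRNA lines lie above control lines over most spacer positions, and in liver not over the first 600 nt.

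In Hepa1c1c7 cells, spacer RNA was about 3 times as deep relative to mature rRNA after Eif3m siRNA, and all 4 spacers were higher. Mean spacer depth was 3.32% ± 0.60 (SD, n = 3) of mean mature depth in control libraries and 9.65% ± 1.66 (SD, n = 3) in Eif3m siRNA libraries, a log2 difference of 1.54 ± 0.21 (SE), or 2.91-fold. The 5′ETS stood at 2.25% ± 0.38 (SD, n = 3) of 18S depth in controls and at 6.72% ± 1.13 (SD, n = 3) after knockdown. ITS2, which separates 5.8S from 28S, went from 6.24% ± 1.16 to 17.2% ± 3.1 of 28S depth (SD, n = 3 each). For ITS1 over 18S the log2 difference was 1.53 ± 0.21 (SE), and for the 3′ETS over 28S it was 1.59 ± 0.19 (SE).

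Every Eif3m siRNA library of the cells lay above every control library in each of these 5 ratios. The exact permutation p was 0.1 for each, the smallest that 3 against 3 allows, and limma on the 13 ratios gave adjusted p between 0.00069 and 0.00078. Depth of 5.8S over 28S was also higher, at 0.278 ± 0.022 against 0.198 ± 0.0066 (SD, n = 3 each; limma adjusted p = 0.0012), but precursor reads lie over the mature regions too, and 5.8S was the shallowest of these. The log2 difference of 0.49 ± 0.07 (SE) became 0.04 ± 0.04 (SE; exact permutation p = 0.4) once spacer depth was subtracted from the mature regions, a test chosen after seeing the data. The balance of the mature subunit rRNAs did not pass the test: 18S over 28S was 1.76 ± 0.075 in controls and 1.76 ± 0.022 after knockdown (SD, n = 3 each), a log2 difference of 0.01 ± 0.04 (SE; exact permutation p = 0.9). Ratios between spacers differed less, with log2 differences of 0.05 ± 0.02 (SE) for 5′ETS over ITS1, 0.07 ± 0.03 for ITS1 over ITS2 and 0.12 ± 0.07 for 3′ETS over ITS2. Groups did not overlap for ITS1 over ITS2, with the smallest possible exact permutation p of 0.1, but limma did not call it (adjusted p = 0.24).

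Along the precursor, limma called 68 of 134 bins higher and 23 lower in Eif3m siRNA cells. All 9 ITS1 bins, all 10 ITS2 bins, all 5 3′ETS bins and 39 of 40 5′ETS bins rose, with median log2 changes of 1.43, 1.38, 1.48 and 1.51. The exception was the bin at 401 to 500, which holds a narrow spike of depth, with a change of 0.36 ± 0.25 (SE). Standard errors of bins, here and below, are limma's and lean on all bins of the fit. The 5 bins with the largest rise all lay in the first 600 nt, from 1.65 ± 0.22 (SE) at 301 to 400 up to 1.91 ± 0.23 (SE) at 501 to 600. As sets of bins, the 4 spacers rose with fry adjusted p = 0.0027 each. Called falls were small and lay in 18S (7 of 17 bins) and 28S (15 of 46), apart from 1 bin across an edge, and the largest was -0.15 ± 0.04 (SE) at 4401 to 4500. These falls follow the settings: with libraries scaled to their mature depth 68 bins were higher and 0 lower, with median-of-ratios scaling 65 and 61, and with limma's eBayes without trend 70 and 1. The lower calls numbered 13, 30 and 7 without control replicate 1, 2 or 3, and 5, 30 and 14 without Eif3m siRNA replicate 1, 2 or 3.

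In liver, spacers were also deeper relative to mature rRNA after Eif3m siRNA, by less than 2-fold, and the change was uneven along the precursor. Mean spacer depth was 0.117% ± 0.013 (SD, n = 3) of mature depth in control livers and 0.185% ± 0.023 (SD, n = 3) in Eif3m siRNA livers, a log2 difference of 0.67 ± 0.14 (SE), or 1.59-fold. Relative to the neighbouring mature rRNA, log2 differences were 0.62 ± 0.15 for the 5′ETS, 0.54 ± 0.12 for ITS1, 0.56 ± 0.13 for ITS2 and 0.68 ± 0.24 for the 3′ETS (SE, n = 3 each). Each of these 5 ratios was higher in all 3 knockdown livers than in any control liver. The exact permutation p was 0.1 for each, again the smallest possible, and limma adjusted p was 0.007 for all but the 3′ETS, for which it was 0.02. The 3′ETS result rests on few reads: with a pseudocount of 10 reads its log2 difference was 0.22 ± 0.18 (SE; exact permutation p = 0.4).

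Liver 18S rRNA was deeper relative to 28S after knockdown. The ratio was 1.48 ± 0.029 in control livers and 1.81 ± 0.045 in Eif3m siRNA livers (SD, n = 3 each), a log2 difference of 0.29 ± 0.03 (SE), or 1.22-fold (exact permutation p = 0.1; limma adjusted p = 0.012). All 17 of the 18S bins were called higher (median 0.18, fry adjusted p = 0.003) and 24 of 46 28S bins lower (median -0.08, fry adjusted p = 0.028). How this change divides between 18S and 28S depends on the scaling: with median-of-ratios scaling the 18S median was 0.01, with 0 bins higher, and the 28S median -0.25. The largest falls lay close together in 28S, at -0.28 ± 0.03 (SE) for 10001 to 10100, -0.25 ± 0.03 for 10101 to 10200 and -0.28 ± 0.03 for 10201 to 10300.

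Spacer segments of the liver did not move together. Depth over the first 650 nt of the 5′ETS was 0.899 ± 0.216 of that over the rest in control livers and 0.496 ± 0.050 in knockdown livers (SD, n = 3 each), a log2 difference of -0.84 ± 0.21 (SE; exact permutation p = 0.1; limma adjusted p = 0.007). The narrow spike named above supplied most of the first part's depth, and leaving it out was a choice made after seeing the data. Without it the rest was 4.0 times as deep as the first part in control livers and 7.68 times in knockdown livers (geometric means). The first part over the rest then differed by -0.94 ± 0.21 (SE). ITS1 over ITS2 was higher after knockdown, at 0.535 ± 0.026 against 0.444 ± 0.030 (SD, n = 3 each), a log2 difference of 0.27 ± 0.07 (SE; exact permutation p = 0.1; limma adjusted p = 0.031). The 5′ part of ITS1 over its 3′ part differed by 0.37 ± 0.20 (SE; exact permutation p = 0.2; 0.20 without control replicate 2), and the same ratio of ITS2 by -0.03 ± 0.05 (SE; exact permutation p = 0.8). Depth of 5.8S over 28S differed by 0.16 ± 0.10 (SE; exact permutation p = 0.3), and by 0.08 without control replicate 2.

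Bins of the liver profile followed the same outline, and limma called 69 of 131 bins higher and 25 lower (43 and 50 with median-of-ratios scaling). Of 40 5′ETS bins 34 rose, and the other 6, which make up the first 600 nt, had changes of -0.23 to 0.14. ITS1 had 8 of 9 bins higher (median 0.84), ITS2 8 of 10 (median 0.45), and in the 3′ETS 2 bins were deep enough to test and neither was called (0.43 and 0.32). The largest rises were 1.17 ± 0.24 (SE) at 3201 to 3300, 1.14 ± 0.20 at 701 to 800, 1.11 ± 0.24 at 1701 to 1800 and 1.10 ± 0.22 at 1801 to 1900 in the 5′ETS, and 1.03 ± 0.26 at 6001 to 6100 in ITS1. Fry adjusted p was 0.015 for the 5′ETS, 0.0062 for ITS1, 0.049 for ITS2 and 0.36 for the 3′ETS. The ITS2 call was lost with median-of-ratios scaling (fry adjusted p = 0.22), and liver spacer depths were low, at 154 to 367 reads per position for ITS2.

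**Figure D2:**
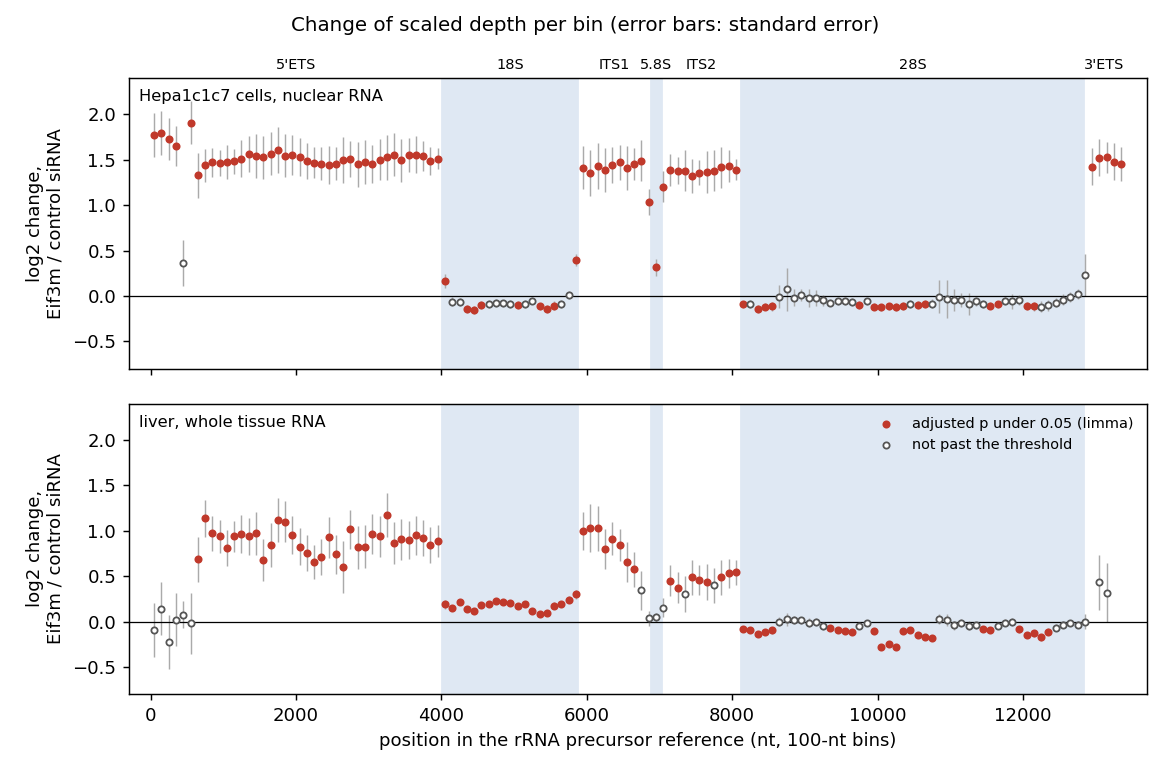
log2 change of scaled depth (Eif3m over control siRNA, 3 libraries each) in 100-nt bins along the precursor, with the standard error from limma as bars, filled points for bins past the threshold, and mature regions shaded. Spacer bins of cells have a median of 1.47, and those of liver a median of 0.82, with the first 600 nt near 0.

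Over both systems, 8 of 13 ratios passed the stratified exact permutation test. All spacers over all mature regions differed by 1.10 ± 0.13 (SE, log2), 5′ETS over 18S by 1.10 ± 0.13, ITS1 over 18S by 1.03 ± 0.12, ITS2 over 28S by 1.01 ± 0.13, 3′ETS over 28S by 1.13 ± 0.15 and ITS1 over ITS2 by 0.17 ± 0.04. Each of these had an exact permutation p of 0.005, the smallest possible, and an adjusted p of 0.011. The ITS1 over ITS2 call was lost with median depths (0.12, exact permutation adjusted p = 0.079). The ratio of 5.8S to 28S differed by 0.32 ± 0.06 (exact permutation adjusted p = 0.028), and by 0.10 (adjusted p = 0.14) once spacer depth was subtracted from the mature regions. Depth over the first 650 nt relative to the rest of the 5′ETS differed by -0.47 ± 0.12 (exact permutation adjusted p = 0.033), a call that was lost without the spike (-0.33, adjusted p = 0.25). Without the spike this ratio changed by 0.28 in cells and by -0.94 in liver, so its mean is not a common change. The ratio of 18S to 28S did not pass (0.15 ± 0.02, exact permutation adjusted p = 0.065), but it passed with median depths (0.15, adjusted p = 0.033) and after that subtraction (0.18, adjusted p = 0.028), and limma gave an adjusted p of 0.041. Its mean joins 0.005 in cells with 0.29 in liver and is not a common change either. The ratio of 5′ETS to ITS1 (0.06 ± 0.04, exact permutation adjusted p = 0.16) also passed with median depths (0.15, adjusted p = 0.011). With signs flipped only within same-numbered replicate pairs, 0 of 13 ratios passed (spacers over mature regions, sign-flip adjusted p = 0.051). That test gives no p below 0.03125 before adjustment, so 0 passing partly reflects its resolution.

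Some of these calls in the exact permutation test changed when 1 library was left out. For the calls that were lost the values moved little, and leaving out a library also leaves the test fewer assignments. The 5.8S call was lost without Eif3m siRNA liver replicate 1 (0.32, adjusted p = 0.056). The call on the first part of the 5′ETS was lost without Eif3m siRNA cell replicate 1 (-0.44, adjusted p = 0.065), Eif3m siRNA cell replicate 3 (-0.45, adjusted p = 0.058) or Eif3m siRNA liver replicate 1 (-0.42, adjusted p = 0.057). Without a control library, ratios that had not passed did so: 18S over 28S without control cell replicate 2 (0.16, adjusted p = 0.019) and 3′ETS over ITS2 without control liver replicate 1 (0.21, adjusted p = 0.024). The bin fit over both systems called 69 bins higher and 28 lower, or 65 and 62 with median-of-ratios scaling and 79 and 12 with mature-depth scaling. All bins of ITS1, ITS2 and the 3′ETS and 39 of 40 5′ETS bins rose, 27 of 46 28S bins fell, and 1 of 17 18S bins was called.

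Whether the response differed between cells and liver was tested directly. By limma on the ratios, which called 8 of 13 differences, liver minus cells was -0.88 ± 0.23 (SE, log2; adjusted p = 0.0086) for spacers over mature regions and 0.29 ± 0.07 (adjusted p = 0.0086) for 18S over 28S. The planned exact permutation test passed 0 of 13 differences, with 1 ratio at an unadjusted p under 0.05, the 5′ over the 3′ part of ITS1 at p = 0.04. It exchanged labels within each system, so a change that both share entered its reference, and a p above the threshold does not show equal changes. With the shared change removed before the exchange, a test chosen after seeing the data, 10 of 13 passed in the permutation test. That form is no longer exact and gave p under 0.05 for 9.94% of ratios simulated with equal changes, and so calls too many. Cell RNA was nuclear and liver RNA was not, so a difference between these systems cannot be separated from the RNA fraction, the dose or the time.

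**Figure D3:**
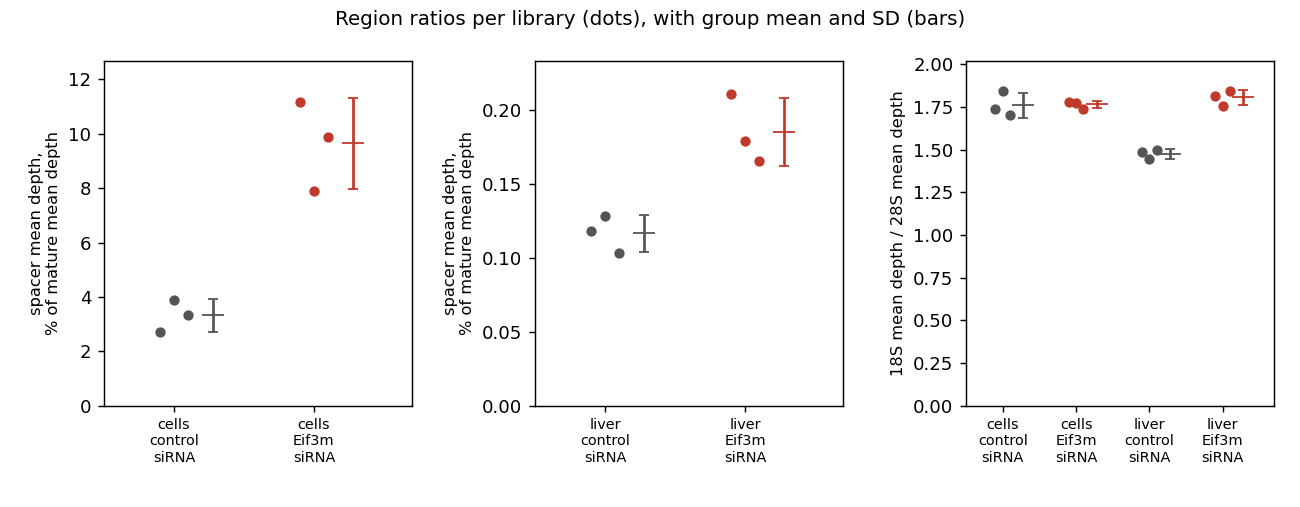
Ratios of mean depth per library (dots), with group mean and SD (bars; n = 3 per group) and axes from 0: spacers as a percentage of mature regions in cells (left) and liver (middle), and 18S over 28S in all 4 groups (right). Eif3m siRNA libraries lie above controls in the left and middle panels, and for 18S over 28S in liver, at 1.76 to 1.85 against 1.44 to 1.5.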

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

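All tests of explanations in this part were chosen after the results were seen; the tests of the difference between liver and cells and the splits of the libraries were planned, apart from those with the shared change removed. The results listed here stand out because the knockdown change differed between liver and cells by limma or fry. The planned exact permutation test of that difference passed 0 of 13 ratios, and 8 of 100 splits gave at least as many differing bins as the real one (57, highest other 79). A change that both systems share widens both references, so the planned tests are strict, and missing the threshold does not show equal changes. With that change removed, 10 of 13 ratios passed, in a form that gave p under 0.05 for 9.94% of ratios simulated with equal changes. With it removed from the bins, 2 of 100 splits, the real one included, gave at least as many calls (56, highest other 70). In 3 of 100 simulations of bins with equal changes the share fell under 0.05. Only 10 of the 100 simulations made any call, and a simulation without calls could not fall under 0.05. That rate therefore does not tell how often profiles with many calls pass, and chance is not excluded for the count of differing bins. The count itself depends on single libraries and settings: of 57 bins 40 were lower in liver, against 21 without control cell replicate 1, 25 without Eif3m siRNA cell replicate 1, 25 without Eif3m siRNA cell replicate 3, 26 without control liver replicate 1 and 63 with a pseudocount of 10.

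Liver minus cells, by limma on the ratios, the log2 change was -0.88 for all spacers over mature regions, -0.96 for 5′ETS over 18S, -0.99 for ITS1 over 18S, -0.90 for ITS2 over 28S, -0.90 for 3′ETS over 28S, -0.33 for 5.8S over 28S, 0.29 for 18S over 28S and -0.74 for the first part of the 5′ETS over its rest. Values over 18S and over 28S are not on 1 scale, because 18S over 28S itself differed. The value for 5.8S over 28S turned to 0.11 ± 0.11 (SE) once spacer depth was subtracted from the mature regions. By fry on bins, the median difference was -0.64 for the 5′ETS, -0.59 for ITS1, -0.93 for ITS2, -1.06 for the 3′ETS, -0.27 for 5.8S and 0.28 for 18S.

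The first pattern is the rise of spacers over mature rRNA. Genomic DNA could raise spacers, and it holds the first 650 nt of the 5′ETS in full. In liver the depth added there was -0.0027 ± 0.043 (SE) of that added to the rest, against 0.248 in control livers, which argues against DNA. In cells it was 0.154 ± 0.029 (SE) against 0.120, near the control profile, so this comparison does not decide there. Scaled depth in cells rose by 272 ± 29 (SE) reads per position in the first part without the spike and by 1765 ± 268 (SE) in the rest. These values argue against evenly covered DNA in cells, while unevenly covered DNA stays open because no DNA profile was measured. Summed depth is argued against, since with it as a covariate the knockdown coefficient was 1.26 ± 0.18 (SE) in cells and 0.77 ± 0.17 (SE) in liver, with 95% intervals above 0. A purer nuclear fraction in the knockdown cells would raise all spacers alike. Their log2 changes spanned 0.12 ± 0.07 (SE, 3′ETS minus ITS2). Differences past 2 SE were 5′ETS minus ITS2 at 0.12 ± 0.03 (SE), ITS1 minus ITS2 at 0.07 ± 0.03 and 5′ETS minus ITS1 at 0.05 ± 0.02, and no pair with the 3′ETS exceeded 2 SE. These small differences are not established. For 5′ETS over ITS1 the groups overlapped (exact permutation p = 0.2, limma adjusted p = 0.38). ITS1 over ITS2 had a limma adjusted p of 0.24, and 5′ETS over ITS2 was not among the 13 ratios. A purer fraction would not account for such differences if they are real. The shared part of the rise stays open because nothing here measures purity. Liver had no nuclear step, and an effect of the knockdown on precursor synthesis or processing stays open in both.

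The second pattern is the higher 18S over 28S ratio in liver. A few deeply covered positions are argued against, since the log2 difference was 0.26 ± 0.03 (SE) without the highest 10% of positions. Precursor reads over 18S are too few, with all spacers at 0.185% of mature depth, and the difference was 0.29 ± 0.03 (SE) after their subtraction. Summed depth is argued against as well, with 0.27 ± 0.03 (SE) as adjusted coefficient. Uneven breakdown of 28S was not tested and stays open, as does an effect of the knockdown on the balance of the subunits.

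The third pattern is the spike at 414 to 449 in the 5′ETS, 36 nt wide. Its mean depth was 773 to 905 in control cells and 917 to 991 in knockdown cells, while flanking depth was 34.6 to 103 and 228 to 339. Precursor reads are argued against as its source, since above its flanks the spike changed by -0.36 ± 0.21 (SE, log2, scaled depth) in cells while the flanks changed by 1.77 ± 0.39 (SE). In liver the spike changed by 0.09 ± 0.09 (SE) and the flanks by -0.19 ± 0.16 (SE), so liver does not tell sources apart. Reads from another sequence that follow the library total would leave the spike near 0 in cells, and it lay between 1 and 2 SE below, so that source stays open; no such sequence was searched for.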

How the results depend on the processing

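The tests without the spike, with 30-nt step windows, with precursor depth subtracted, without the highest 10% of mature positions and with the shared change removed were chosen after seeing the data; the other alternatives were planned. Of 949 ratio results under alternatives, 865 kept their direction and side of the threshold, 30 changed sign, 16 no longer passed and 38 newly passed. The 949 include exact tests within cells or within liver, which cannot pass under any setting. For those only the direction could change, so 865 overstates how stable the calls were. Before any alternative, results that changed sign were at most 0.33 in size, none of these had passed in the exact permutation test, and the cause was not tested unless named. With median depths, values turned to 0.014 (3′ETS/ITS2, liver minus cells), 0.36 (first part of the 5′ETS over its rest, cells) and, for the 5′ over the 3′ part of ITS2, 0.10 (liver), 0.0084 (both) and 0.18 (liver minus cells). Trimmed edges gave -0.0012 (18S/28S, cells) and -0.0096 (5′ETS/ITS1, liver minus cells), and a pseudocount of 10 reads, which weighs on the shallow 3′ETS, gave -0.037, -0.31 and -0.17 for 3′ETS/ITS2 in cells, liver and both. The spike left out gave 0.28 for the first part of the 5′ETS in cells, subtraction 0.11 for 5.8S/28S (liver minus cells), and the highest positions left out -0.0021 for 18S/28S in cells. Without 1 library at a time, values that changed sign ran from -0.019 to 0.039 (18S/28S, cells), -0.10 to 0.18 (3′ETS/ITS2, liver minus cells), -0.026 to 0.085 (5′ETS/ITS1, liver minus cells) and, for the parts of ITS2, -0.051 to 0.033 (cells), -0.054 to 0.018 (liver), -0.039 to 0.0043 (both) and -0.059 to 0.028 (liver minus cells). Spacers over mature regions ran from 1.40 to 1.68 in cells, 0.57 to 0.74 in liver and 1.04 to 1.17 over both, and ratios passing over both systems from 6 to 9. limma on the ratios newly passed spacers over mature regions in cells (1.54), liver (0.67) and liver minus cells (-0.88), and called 6, 8 and 8 of 13 ratios there; within cells or liver an exact test of 3 against 3 cannot pass. With the shared change removed, liver minus cells (-0.88) newly passed, with 10 of 13 ratios against 0. Pairing by replicate number was not evident, though 3 same-numbered pairs per system are too few to rule it out. Correlations of same-numbered deviations over bins were -0.82, -0.75 and 0.05 in cells and 0.23, -0.15 and 0.39 in liver. With a replicate block, spacers over mature regions stood at 1.10 over both systems (sign flips of same-numbered pairs, adjusted p = 0.051), and 0 of 13 ratios passed. The sign-flip test gives no p below 0.03125 before adjustment over 13 ratios, so 0 passing partly reflects its resolution. With the block, fry in liver had adjusted p = 0.057 for ITS2, 0.087 for 28S and 0.022 for the 3′ETS (without the block 0.049, 0.028 and 0.36). With the block, fry also called 3 regions for the difference between systems against 6, with 40 differing bins. Called bins in cells, liver, both and for the difference numbered 91, 94, 97 and 57, the last 38 to 71 without 1 library at a time. They numbered 178, 183, 191 and 110 with 50-nt bins and 48, 47, 48 and 29 with 200-nt bins, as the number of bins changes, and 1, 25, 15 and 2 among spacer bins scaled to spacers, which removes a shared rise. Without trend, eBayes called 70 bins higher and 1 lower in cells and 62 and 14 in liver. Median-of-ratios scaling moved the median of all bins from 0.34 to 0.0018 in cells and from 0.18 to 0.01 in liver, and left 3 of 7 regions called in liver. Keeping positions at a depth ceiling was not run, as no position lay at one. Depth limits the liver 3′ETS most, at 5.37 to 16.5 reads per position.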

Other observations

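The tests of hypotheses in this part were chosen after the data were seen; the counts of splits were planned. In liver the change after Eif3m siRNA varied along the precursor. Scaled to summed depth, log2 changes were -0.04 ± 0.23 (SE) in the first 650 nt of the 5′ETS without the spike, 0.89 ± 0.17 in the rest of the 5′ETS, 0.95 ± 0.14 in the 5′ part of ITS1, 0.58 ± 0.16 in its 3′ part, 0.43 ± 0.13 and 0.46 ± 0.15 in the 5′ and 3′ parts of ITS2 and 0.57 ± 0.25 in the 3′ETS. In cells the same segments, in the same order, changed by 1.78 ± 0.28, 1.5 ± 0.20, 1.41 ± 0.20, 1.46 ± 0.21, 1.37 ± 0.21, 1.38 ± 0.19 and 1.5 ± 0.17. Mean depth over the first segment in liver was 11.8 to 22.5 in controls and 14.4 to 26.5 after knockdown, so its change rests on few reads.

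A hypothesis from the liver profile is that precursor RNA holding the 5′ETS beyond 650 nt and the 5′ part of ITS1, as intermediates of the 18S branch do, rose more than precursor RNA holding ITS2. In liver the rest of the 5′ETS over ITS2 was higher after knockdown by 0.45 ± 0.04 (SE, log2) and the 5′ part of ITS1 over ITS2 by 0.50 ± 0.19 (SE), but these segments were picked from the same profile, so the ratios restate it and do not test the hypothesis. In cells, which were not used to pick them, the first ratio was higher by 0.12 ± 0.03 (SE), and the second by 0.038 ± 0.030 (SE), with control and knockdown libraries overlapping, so the hypothesis stays open. Depth does not tell which molecules carried the reads, and decay products of the spacers may give the same pattern.

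In the first 650 nt without the spike, the rest of the 5′ETS over its first part went from 8.51 to 6.99 in cells (geometric means) and from 4.0 to 7.68 in liver. The difference between systems was 1.22 ± 0.25 (SE, log2).

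Log2 changes of the 131 bins tested in both systems correlated across bins (Pearson r = 0.80, Spearman rho = 0.73), with control libraries that the systems do not share. Within the 61 spacer bins r was -0.0044 (rho = 0.13) and within the 64 mature bins 0.15 (rho = 0.34). Bins are not independent replicates.

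Other splits of the libraries were counted for the bin and region calls. Over both systems, 1 of 100 splits, the real one, gave 97 called bins, with 80 as the highest other. For regions, 2 of 100 splits, the real one included, gave 6 called regions, so another split matched the real count. Each share lies under 0.05, which argues against chance but does not exclude it, and less so for regions. Within cells (91 bins and 6 regions) and within liver (94 bins and 5 regions), the highest other split called 0, and 10 splits are too few for a share under 0.05.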
